A study of Homo sapiens with 2 samples.

How the data were processed

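Total RNA of SK-ES1 cells was extracted with Trizol, per the labels' protocols, amplified and biotin-labelled with an Illumina TotalPrep kit, and hybridised to Illumina expression BeadChips. The samples were 1 array of wild type cells and 1 array of radiation-adapted cells, grouped by their titles in the labels. The authors deposited, for each probe and array, an average bead signal intensity on a linear scale that was neither background-subtracted nor normalized, per the file headers, and a detection p-value against the array's own negative controls, also per the file headers. The scanner and the summarising software are not given in the sources used here. The authors also deposited a table of processed intensity values whose making is not stated. Compared with the raw signals, its sorted columns were equal within 0.2, both medians were 10.6, values ran from -28.6 to 27679.4, and each column kept the order of its array (Spearman correlation over probes 0.999998 and 0.999997). It was therefore read as linear, background-subtracted, quantile-normalized between the arrays and not centred, an inference from the values, and was used as an alternative only.

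The raw signals were processed with limma 3.58.1 in R 4.3.3: the neqc function fitted the normexp background model from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. The offset makes the folds of dim genes smaller than they are. Later steps used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Probe names came from the platform annotation held by GEO and gene symbols from a RefSeq table of assembly GRCh38.p14. Of 47323 probes, 30113 had 1 gene symbol, 8 had several and 17202 were not named here; probes with several or no gene entered no comparison of genes. A current entry was not found for 39 symbols, which kept the annotation's name. The array files name no genome build, so the RefSeq table was used only for names, gene classes and the order of genes.

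A gene was represented by its probe with the highest mean log2 signal and counted as detected with a detection p-value under 0.01 on at least 1 array. The log2 ratio was radiation-adapted minus wild type, and a gene with a measured ratio of 2-fold or more was counted as higher or lower. With 1 array per group there was no spread between replicates and no test. The only repeat of a gene's ratio was a further probe on the same arrays, which holds isoform differences and measurement error but not the spread between cultures. The number of arrays limits the precision. A gene not detected on 1 array was given as at least N-fold, the bright signal over the higher of the lowest detected signal of the other array and the gene's own signal there. This value holds no allowance for measurement error, so it is not a firm minimum, and values close to 1 are uncertain.

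The groups, the size rule, the 39 gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. The lists covered targets of EWSR1-FLI1, DNA repair and damage signalling, cell cycle, stress, metabolism, signalling, differentiation, references and markers of other cell types. The named genes were the 15 highest and the 15 lowest detected on both arrays whose other detected probes had the same sign, the 5 highest and 5 lowest detected on 1 array, up to 4 genes at 2-fold or more from each list (or the 2 largest where it had none), and ACTB and GAPDH. Uncharacterised names were passed over. Some genes that this rule takes are not reported here. RNA28SN5, CDKN1A, SREBF2, HSPA5, CRELD2, PDIA4, CALR, EDEM1 and HSP90B1 fell outside this rule and were chosen after their values were seen. The median ratio of each list with at least 5 detected members was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression.

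Classes of RNA and chromosomal regions were examined after the values had been seen. For regions, the median ratio of 50 neighbouring protein-coding genes detected on both arrays was compared with the farthest window of 1000 shuffled gene orders, and windows beyond that of 95% of the orders made a region, so that a small number of shuffled windows as far follows from this choice. Regions were also found on every other gene, with windows of 25 genes, and measured on the genes left out. Alternatives left out the background correction, scaled by the median in place of quantiles, used an offset of 50, used the authors' processed values, changed the detection filter or the size rule, or took the median of a gene's probes. Protein-coding genes alone, genes outside the regions, and genes detected on 1 array at their bound were alternatives chosen after seeing the data.

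The steps were tested on simulated data in which 200 of 11483 genes differed between a pair of simulated arrays. At 2-fold or more, 0% of genes simulated at 1.5-fold, 32% at 2-fold, 94% at 3-fold and 96% at 4-fold were called, and 0.0975% of unchanged genes. The simulated multiplicative noise was smaller than the SD per probe of 0.329 in these data, which also holds isoform differences. No spread between cultures was simulated. These shares therefore do not give the rate of false calls in these data. Of 100 random lists without a difference, 4 lay outside the central 95%.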

Results

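Gene expression was measured in SK-ES1, an Ewing sarcoma cell line that carries the EWSR1-FLI1 fusion, a transcription factor made by a chromosomal translocation. Total RNA of wild type cells and of a radiation-adapted derivative, whose label carries the value 4 Gy, was hybridised to Illumina expression BeadChips. Each group held 1 array, so there were no replicates: the differences given here have no replicate check, and no test or p-value was made from probes or genes. The labels do not say how the radiation of 4 Gy was given, and the comparison asks how the radiation-adapted cells differed from wild type cells.

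Both arrays held 47323 probes. The median raw signal was 137 on the wild type array and 139.3 on the radiation-adapted array. Detection p-values under 0.01 were given to 15887 probes (33.6%) of the wild type array and to 15399 probes (32.5%) of the radiation-adapted array, which gave 9740 and 9593 detected genes. Of 10189 genes detected on at least 1 array, 9144 were detected on both, 596 on the wild type array alone and 449 on the radiation-adapted array alone. Across the 9144 genes the normalized log2 signals of the arrays had a Pearson r of 0.969 and a Spearman correlation of 0.960, and genes are not independent replicates.

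In the radiation-adapted cells, transcripts of cholesterol synthesis, immediate early genes, and TGF-beta and BMP targets were higher than in wild type cells. Signals of small nuclear, nucleolar and ribosomal RNAs were also higher, but a technical difference in how such RNA was recovered or primed stays open. The list of unfolded protein response genes and ATF4 targets was lower, with a median log2 ratio of -0.39 and 6 of 22 genes above 0. Gene lists of DNA replication, mitosis and homologous recombination were also lower, with medians of -0.34, -0.30 and -0.44. These medians are under 2-fold. HMGCS1, which makes the precursor of mevalonate, was 5.01-fold higher, and FOS, a subunit of the AP-1 transcription factor, was 6.30-fold higher. DDIT3, which encodes the stress-induced transcription factor CHOP, was 4.60-fold lower, and the chemokine gene CCL20 was at least 8.58-fold lower, since it was not detected in the radiation-adapted cells.

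By the fixed size rule, 410 genes (4.02% of those detected) had a measured ratio at least 2-fold higher in the radiation-adapted cells and 211 (2.07%) one at least 2-fold lower. Counts at 2-fold or 4-fold use measured ratios unless a bound is named. Of these genes, 253 higher and 125 lower were detected on both arrays. With genes detected on 1 array at their bound, 299 were at least 2-fold higher and 140 at least 2-fold lower. At 4-fold the counts by measured ratio were 42 higher and 8 lower. The median log2 ratio of all detected genes, radiation-adapted minus wild type, was -0.04. The counts moved with the background correction: without it, 98 genes were higher and 27 lower, a split further from even than the 410 and 211 above. Where 2 or more probes of a gene were detected, the log2 ratios of the 2 brightest differed with an SD of 0.466 over 2567 genes, and this SD was 0.610 among the dimmest probes. Of 122 genes at 2-fold or more with another detected probe, 100 (82.0%) had all other probes on the same side of 0, compared with 66.1% of genes under 2-fold.

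**Figure D1:**
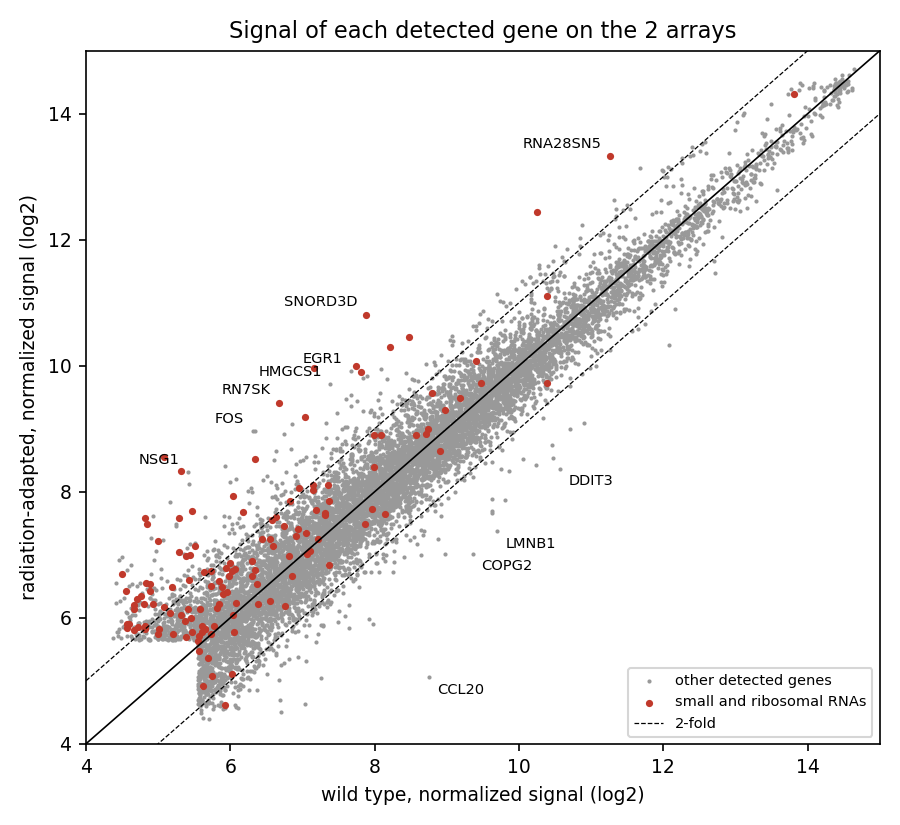
Normalized log2 signal of each of 10189 detected genes on the wild type array (x axis) and on the radiation-adapted array (y axis), with small and ribosomal RNAs in red, the line of equal signal solid and the 2-fold lines dashed. Above the upper dashed line lie 410 genes and below the lower one 211.

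Among genes detected on both arrays and named by the size rule, those highest in the radiation-adapted cells were in large part small RNAs. SNORD3D and SNORD3A, copies of the U3 RNA that guides ribosomal RNA processing, were 7.65-fold and 6.96-fold higher, and RN7SK, which holds back transcription elongation, was 6.70-fold higher. The spliceosomal RNA RNU1-3 (4.75-fold), the 18S ribosomal RNA RNA18SN5 (4.55-fold), the RNase P RNA RPPH1 (4.49-fold) and the 5S ribosomal RNA RNA5S9 (4.46-fold) followed. The copies of U3 and of U1 are nearly identical in sequence, so the share of each copy is uncertain. Among protein-coding genes, the lens crystallin gene CRYGS was 6.19-fold higher, CPNE4 5.60-fold, the early response transcription factor EGR1 4.76-fold, the transcription factor KLF2 4.52-fold and ZCCHC12 4.46-fold. Of genes detected on the radiation-adapted array alone, SNORD3C was at least 7.96-fold higher, the minor spliceosome RNA RNU11 at least 6.84-fold, the neuronal vesicle gene NSG1 at least 6.76-fold, LIMCH1 at least 5.91-fold and the phospholipase gene PLA2G3 at least 4.89-fold.

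The lowest genes detected on both arrays were COPG2, a subunit of the coat of Golgi vesicles, at 5.10-fold lower, and LMNB1, a lamin of the nuclear envelope, at 5.02-fold lower. SESN2, a stress-induced regulator of growth signalling, was 4.23-fold lower. CTH, an enzyme of cysteine synthesis, was 3.83-fold lower, with its other 2 detected probes also lower. TMEM119 was 3.88-fold lower and CDC42EP1 3.51-fold. ZNF664 was 3.81-fold lower, the exon junction gene MAGOH 3.50-fold, MYDGF 3.50-fold, the chromatin gene ING3 3.38-fold and ARPC3, a subunit of the actin-branching complex, 3.35-fold. PDIA3P1 (3.89-fold lower) is a pseudogene and NBPF9 (3.84-fold lower) belongs to a family of near-identical genes, so both values are uncertain. Of genes detected in wild type cells alone, CCDC71 was at least 3.03-fold lower, VLDLR-AS1 at least 2.90-fold, CIP2A, an inhibitor of a phosphatase, at least 2.62-fold and the receptor gene TNFRSF4 at least 2.62-fold lower.

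Of 39 gene lists fixed in advance, 34 had at least 5 detected members. Against 10000 random lists of the same size and mean expression, 8 list medians lay above the central 95% and 4 below. Random draws of unrelated genes would put 1.7 lists outside. Some lists share members, and genes of a list can vary together, so 1.7 may be too low for such lists. The positions of the lists describe the 2 arrays and are not tests of the lines. With genes detected on 1 array set at their bound, the medians of these 12 lists were the same.

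Cholesterol synthesis stood highest. Of 16 detected genes, 15 were higher in the radiation-adapted cells, 6 of them at least 2-fold and none at least 2-fold lower, and the median log2 ratio of 0.81 was above all 10000 random lists. The exception was the regulator gene SREBF2, at least 1.18-fold lower, with a signal near the detection limit. Beside HMGCS1, the log2 ratio was 1.77 for DHCR7, the last step of the pathway, 1.41 for MSMO1 and 1.25 for LSS, which closes the sterol ring. TGF-beta and BMP targets had a median of 0.72 over 12 genes, also above all 10000 random lists, with 2 at least 2-fold higher (PMEPA1, 1.30, and ID1, 1.09) and 1 lower by measured ratio, LTBP2, whose bound was 1.16-fold. Of 16 immediate early genes and AP-1 members, 5 were at least 2-fold higher and 1, ATF3, at least 2-fold lower (-1.62), with a median of 0.46 at percentile 99.9. The MAP kinase feedback gene SPRY4 was among the higher ones, at least 2.31-fold. With 1 array per line, the state of the culture at harvest cannot be told apart from adaptation for immediate early genes. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had a median of 0.70 over 10 genes, above all 10000 random lists. Of the 10 genes, 8 were above 0. H2AC18 (1.44), H2AC6 (1.33) and H2BC5 (1.23) were at least 2-fold higher, and 3 of the 10 genes lay in the chromosome 1 region described further on. Among named list genes, COL1A2, MSMO1, PAX7 and DCLRE1C had another detected probe on the other side of 0, which makes their ratios uncertain.

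Targets that EWSR1-FLI1 represses were higher as a group. Of 17 detected, 15 were above 0, with a median of 0.44 at percentile 99.8. FSTL1 (1.31) and the collagen gene COL1A2 (1.10) were at least 2-fold higher, and the WNT antagonist gene DKK1, past 2-fold by measured ratio, was at least 1.86-fold higher. Targets that the fusion activates had a smaller median of 0.11 over 31 genes, at percentile 98.7, with 22 above 0 and none at 2-fold in either direction. The ends of that list were PAX7 (0.94) and NKX2-2 (-0.68), both transcription factors. Neural differentiation genes had a median of 0.44 over 11 genes (percentile 99.5) with 1 at least 2-fold higher, STMN2 (1.27), and the list moved to percentile 96.9 without background correction. Interferon-stimulated genes had a median of 0.24 over 19 genes (percentile 97.8), with 2 at least 2-fold higher, the virus-tethering gene BST2 (1.68) and OAS3, at least 2.05-fold. Over genes detected on both arrays this list stood at percentile 97.1, inside the central 95%.

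The list of unfolded protein response genes and ATF4 targets was lower than all 10000 random lists, with a median of -0.39 over 22 genes. Of these, 9 were at least 2-fold lower, 6 were above 0 and none was at least 2-fold higher. DDIT3 (-2.20), SESN2 (-2.08), the transcription factor XBP1 (-1.72) and ATF3 (-1.62) had the largest differences. The 6 genes above 0 were HSPA5 (0.73), CRELD2 (0.30), PDIA4 (0.26), CALR (0.09), EDEM1 (0.09) and HSP90B1 (0.03). Homologous recombination and Fanconi anaemia genes had a median of -0.44 over 19 genes (percentile 0.05), with 3 above 0 and 1 at least 2-fold lower, NBN (-1.13), which senses double-strand breaks. DNA replication and G1/S genes had a median of -0.34 over 26 genes (percentile 0.01), with 6 above 0 and none at 2-fold. The largest values were those of the ribonucleotide reductase gene RRM2 (-0.74) and of the helicase gene MCM2 (0.81). G2/M and mitosis genes had a median of -0.30 over 28 genes (percentile 0.02), with 4 above 0 and 1 at least 2-fold lower, the mitotic kinase gene PLK1 (-1.04). Whether the lower homologous recombination list was separate from the lower replication and mitosis lists was not tested.

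**Figure D2:**
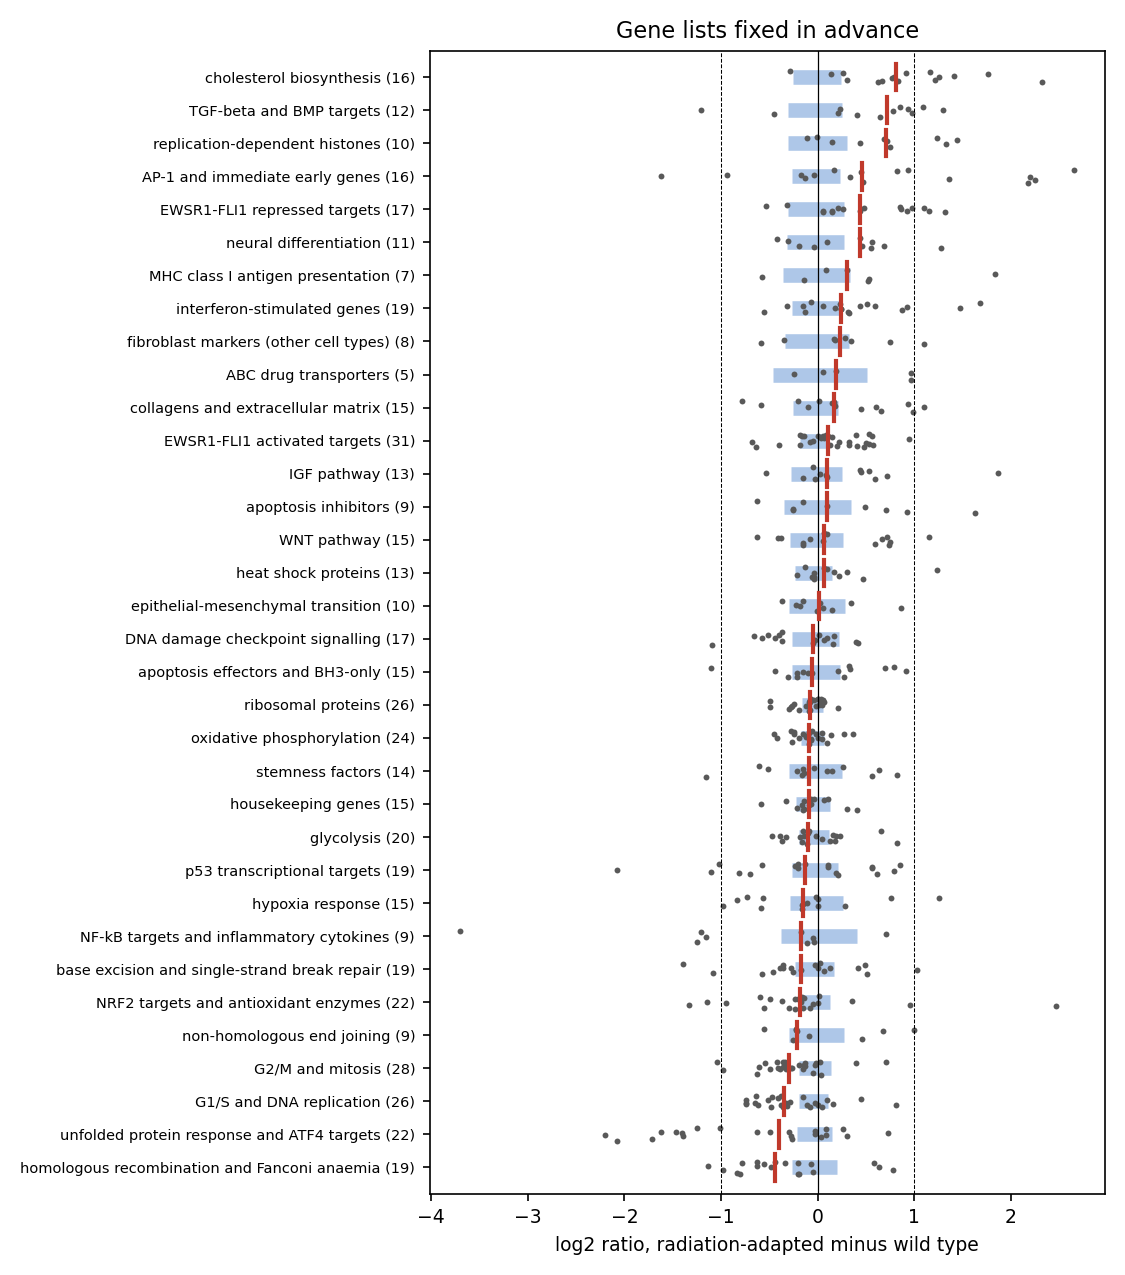
Log2 ratio (radiation-adapted minus wild type) of each detected member (points) of the 34 lists with at least 5 detected genes, with the number of members in brackets, the list median in red and the central 95% of 10000 random list medians in blue. Cholesterol synthesis lies highest at a median of 0.81 and homologous recombination lowest at -0.44, and dashed lines mark 2-fold.

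The other DNA repair and damage lists lay inside the central 95% of random lists. Base excision repair had a median of -0.18 over 19 genes (percentile 9.3), with the glycosylase genes NEIL3 (-1.39) and UNG (-1.09) lower and MBD4 (1.03) higher by at least 2-fold. Non-homologous end joining had a median of -0.21 over 9 genes (percentile 11.0), none at 2-fold, and its largest values were those of DCLRE1C (0.99) and TP53BP1 (0.68). DNA damage checkpoint genes had a median of -0.05 over 17 genes (percentile 46.7), with RAD17 (-1.09) at least 2-fold lower. Transcriptional targets of p53 had a median of -0.13 over 19 genes (percentile 22.3), or -0.02 with genes detected on 1 array at their bound. Over the 15 targets detected on both arrays the median was 0.11 (percentile 87.9), so the direction of this list depended on the filter. Among the 19 targets, SESN2 and the apoptosis gene BAX (-1.10) were at least 2-fold lower and DDB2 was at least 1.84-fold lower, while the cell cycle inhibitor gene CDKN1A was at least 1.67-fold higher. Apoptosis effectors had a median of -0.05 over 15 genes (percentile 43.6), with BAX the 1 gene at 2-fold. Apoptosis inhibitors had a median of 0.10 over 9 genes (percentile 75.5), with MCL1 (1.63) higher.

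Antioxidant and NRF2 target genes had a median of -0.19 over 22 genes (percentile 4.3), with NQO1 (-1.33) and HMOX1 (-1.15) lower and AKR1C3 at least 2.58-fold higher. This list stood outside the central 95% over genes detected on both arrays (percentile 1.3) and without the regions described further on (percentile 1.8). Of 9 NF-kB targets and cytokines, 4 were at least 2-fold lower by measured ratio and 1 was above 0: beside CCL20 these were NFKB1 (-1.25), the adhesion gene VCAM1 (-1.16) and RELB, at least 2.17-fold lower. The median of that list was -0.17 (percentile 20.1). MHC class I genes had a median of 0.30 over 7 genes (percentile 96.4), with the peptide loading gene TAPBP (1.84) higher, and stood at percentile 99.1 without background correction and 98.3 over genes detected on both arrays. Collagen and matrix genes had a median of 0.17 over 15 genes (percentile 95.2), COL1A2 being the 1 gene at 2-fold. The IGF pathway had a median of 0.10 over 13 genes (percentile 84.7), with IGFBP5 (1.87) higher, and a median of 0.27 (percentile 98.65) without the regions. The WNT pathway had a median of 0.07 over 15 genes (percentile 73.4), with DKK1 the 1 gene past 2-fold by measured ratio and none at the bounds.

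Epithelial-mesenchymal transition genes had a median of 0.01 over 10 genes (percentile 60.8), with SPARC at 0.86 and CDH11 at -0.37. Stemness factors had a median of -0.09 over 14 genes (percentile 37.2), and PROM1 was at least 1.33-fold lower. Hypoxia genes had a median of -0.15 over 15 genes (percentile 16.3), with ADM (1.26) higher. For glycolysis the median was -0.10 over 20 genes (percentile 24.9), with PFKFB3 (0.82) and PFKM (0.65) farthest from 0. For oxidative phosphorylation it was -0.09 over 24 genes (percentile 26.7), with NDUFV1 at -0.45 and NDUFB9 at -0.42. Heat shock genes had a median of 0.06 over 13 genes (percentile 88.9), with HSPA1B, a near-identical copy of another gene, at 1.24. For 5 ABC transporter genes it was 0.19 (percentile 79.8), with ABCC5 and ABCA2 both at 0.97. Cancer-testis antigens were detected for 4 of 20 genes, with SSX2 at 1.17, MAGEA12 at least 1.04-fold lower and a median of 0.29, or 0.30 at the bounds. The medians of apoptosis effectors, apoptosis inhibitors, epithelial-mesenchymal transition genes, stemness factors and cancer-testis antigens each changed sign under at least 1 alternative.

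As references, ACTB was at -0.07 and GAPDH at -0.09. Housekeeping genes had a median of -0.09 over 15 genes (percentile 26.6), with PPIA at -0.59 and POLR2A at 0.41. Ribosomal protein genes had a median of -0.08 over 26 genes (percentile 34.6), with RPL37 at -0.50 and RPL13 at -0.49. Markers of other cell types were detected in small numbers. Of 12 fibroblast markers 8 were detected, with a median of 0.23 (percentile 93.4) and COL1A2 the 1 gene at 2-fold. Epithelial markers were detected for 3 of 14 genes, with a median of -0.18 (MUC1 -0.31, EPCAM -0.18), and leukocyte markers for 4 of 14, with a median of 0.13, or 0.20 at the bounds, and CORO1A at least 1.43-fold lower. The 1 detected endothelial marker, EMCN, was at -0.01 and the 1 detected skeletal muscle marker, TNNT1, at -0.16.

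Signals of small and ribosomal RNAs were higher on the radiation-adapted array, with a median above 0 in each of their classes. Whether the cells held more of these RNAs or the sample yielded more of them was not settled. This grouping by RNA class was made after the values were seen. Of 136 such genes, 117 were above 0, and by measured ratio 49 were at least 2-fold higher and 1 at least 2-fold lower. At the bounds these counts were 31 and 0. Their median was 0.72, above all 10000 random lists, and 0.52 with genes detected on 1 array at their bound. Without background correction it was 0.28, and each class median stayed above 0 under the 4 other normalizations. The 3 ribosomal RNA probes were at 2.06 (28S), 2.19 (18S) and 2.16 (5S). By measured ratio 11 of 13 small nuclear RNAs were at least 2-fold higher (median 2.09), 6 of 12 small Cajal body RNAs (median 1.03) and 25 of 100 small nucleolar RNAs (median 0.53), and 1 small nucleolar RNA was at least 2-fold lower. At the bounds 10, 5 and 12 of them were at least 2-fold higher and none lower. The 4 Y RNAs had a median of 0.86. By contrast, the medians were 0.05 for 152 long non-coding RNAs, -0.28 for 26 microRNA genes and -0.04 for 9705 protein-coding genes. Protein-coding genes alone gave 338 higher and 197 lower genes at 2-fold.

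**Figure D3:**
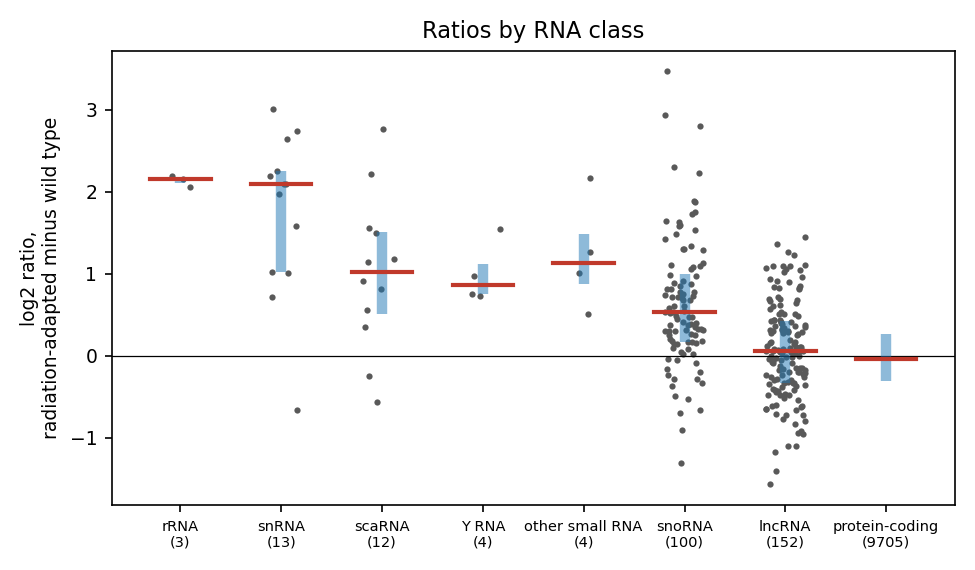
Log2 ratio (radiation-adapted minus wild type) by RNA class, with the number of detected genes in brackets, genes as points (not drawn for protein-coding genes), quartiles in blue and medians in red. Among the classes drawn, which leave out microRNA genes, the median is 2.16 for ribosomal RNA and -0.04 for protein-coding genes.

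Neighbouring genes on several chromosomes differed together, a comparison that was also added after the values were seen. On chromosome 1, between NBPF10 and ELF3, 175 of 233 protein-coding genes detected on both arrays (75.1%) were higher in the radiation-adapted cells, with a median of 0.33, compared with 45.5% of all genes outside it. On chromosome 17, from DCAKD to TBCD, 56 of 241 genes (23.2%) were higher, with a median of -0.33. On chromosome 4, from FAM241A to HAND2, the median of 78 genes was -0.27. Regions were taken where windows of 50 genes lay beyond the farthest window of 95% of 1000 shuffled gene orders. No window in the 1000 shuffled orders was as far from 0 as the farthest windows of these 3 regions. Smaller regions were reached in some shuffles. For chromosome 3 (TMEM39A to MSL2, higher) 20 of 1000 shuffles were as far. For chromosome 1 (NOC2L to PIK3CD, lower) it was 8 of 1000, and for chromosome 8 (TRAM1 to DPY19L4, lower) 30 of 1000. In the search on every other gene, none of these smaller regions was found. A higher chromosome 3 segment found there, SOX2 to XXYLT1, lay elsewhere. That search did find lower segments overlapping the chromosome 4 and 17 regions on each set of genes. Without the genes of the regions on chromosomes 1, 4 and 17, 380 genes were higher and 194 lower at 2-fold, and the interferon list moved to percentile 96.95, inside the central 95%.

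**Figure D4:**
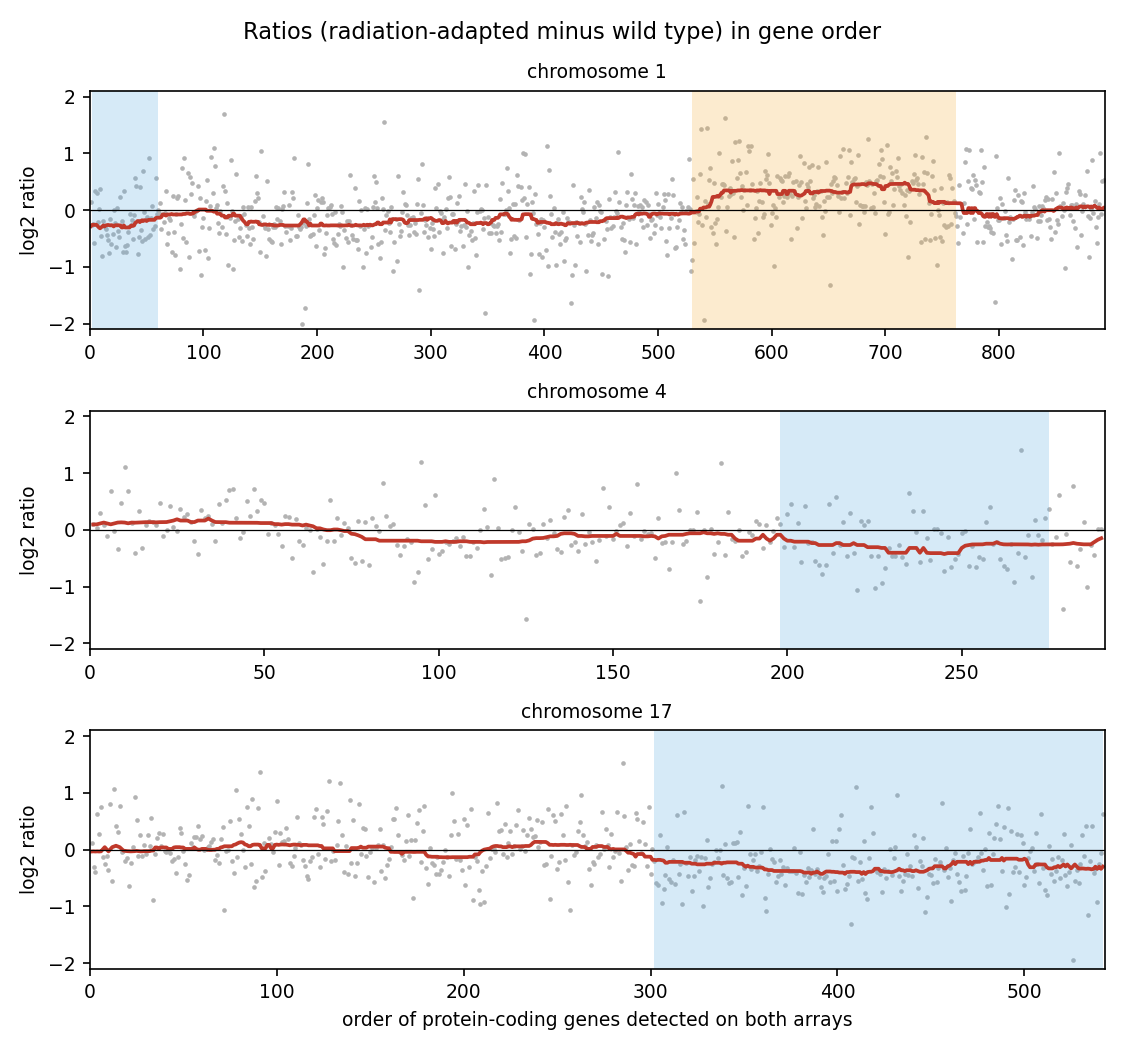
Log2 ratio (radiation-adapted minus wild type) of protein-coding genes detected on both arrays, in gene order along chromosomes 1, 4 and 17 (points, drawn at 2 or -2 where beyond), with the running median over 50 genes in red and the higher region shaded orange and lower regions blue. The region medians are 0.33 on chromosome 1, -0.27 on chromosome 4 and -0.33 on chromosome 17. The lower region at the start of chromosome 1 is at -0.26 and was not found in the search on every other gene.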

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

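The tests of signal near background, the test of poly(A)-lacking transcripts, that of the chance order of genes and all region analyses were chosen after the result was seen. Among probes with no gene name here, which the comparisons did not use, 164 had a measured ratio at least 2-fold higher in the radiation-adapted cells and 296 were detected on the radiation-adapted array alone. These signals stood out because they lie in data outside the main measurement. The counts in the other direction were 89 lower and 473 detected on the wild type array alone, of 3481 unnamed probes detected.

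Signals of small and ribosomal RNAs were higher in the radiation-adapted sample. Signal near background was argued against, as the whole cause, since 17 of these genes with a log2 signal of 8 or more on both arrays had a median of 0.51, which 0 of 10000 random sets of such genes reached, and 18 with such a signal in wild type cells one of 0.41, against 0.72 over all. Higher transcript levels of snoRNA host genes were argued against as well, for 36 snoRNAs. Their 20 host genes had a median of -0.23, and 35 of the 36 snoRNAs lay above their host. Transcription itself was not measured, and small RNAs outside these pairs were not covered. A technical explanation stays open: non-polyadenylated RNA may have been recovered or primed more in the radiation-adapted sample. Replication-dependent histones outside the chromosome 1 region exceeded the polyadenylated replacement histones by 0.91 in the median. The 7 replication-dependent genes ran from -0.01 to 1.33, so they were not higher throughout. Poly(A) tails were not measured, so this difference cannot show that poly(A)-lacking RNA was recovered or primed more. More small RNA in the cells themselves was not tested, and these arrays cannot tell it apart from more recovery or priming.

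Genes of the chromosome 1 region were higher together. Chromosome 1 segments were found on every other gene and measured on the genes left out. A chance order of genes was argued against for the 4 higher segments. In each, 0 of 10000 random gene sets had a median as high as the left-out genes. A lower segment, from ATG4C to AMY1A, was also found on chromosome 1, and 171 of 10000 random sets reached its median of -0.17. Family genes that share probe signal were argued against too, since 181 genes of the region without a shared name stem had a median of 0.35. A dosage difference over the whole region is a candidate explanation: the lower quartile of the left-out genes in the higher segments was shifted by at least 0.33. DNA was not analysed here, and whether such a difference goes with radiation or with separate growth of the lines was not tested.

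The median of the list of ATF4 targets and unfolded protein response genes was lower, with 6 of its 22 genes above 0, and sterol genes were higher. Differences over chromosomal regions were argued against for the ATF4 list, whose median was -0.41 after the running median of neighbours was subtracted. Signal near background was argued against for the sterol list, since 6 members with a log2 signal of 8 or more on both arrays had a median of 0.75, which 4 of 10000 random sets of such genes reached. The state of the culture at harvest, such as density or medium, cannot be told apart from the adaptation, because there was 1 array per line. This holds for the other lists as well, immediate early genes among them. A lasting difference of the radiation-adapted line also stays open.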

How the results depend on the processing

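The alternatives with protein-coding genes alone, without the regions and with genes detected on 1 array at their bound were chosen after the result was seen. With 1 array per group, leaving out a replicate was not possible. The counts of 410 higher and 211 lower genes became 98 and 27 without background correction, 213 and 70 with an offset of 50, 253 and 125 with detection on both arrays, 299 and 140 at the bounds, 1272 and 977 at 1.5-fold, and 42 and 8 at 4-fold. The last 4 follow from a narrower or wider rule, a larger offset or uncorrected background pulls ratios toward 0, and no other cause was tested. The other alternatives stayed within 1.5 times of both counts, from 338 to 439 higher and from 188 to 247 lower. No gene of the 621 changed sign in any alternative in which it was counted. These genes were picked for large ratios and the alternatives reuse the same 2 arrays, so reversals were unlikely from the start. The SD between probes of a gene was 0.466 and became 0.287 without background correction.

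Of list medians under alternatives, 337 stayed inside the 95% interval of the main median and 14 left it, all in marker lists of 1 or 3 detected genes. The interval of a list of 1 gene has no width, so any change leaves it. The cause was not tested for the epithelial list. Across all lists 12 medians, of 9 lists, changed sign, none of them among the 12 lists outside the central 95%. The p53 target median became 0.11 and the stemness median 0.03 with detection on both arrays, and the stemness median 0.09, the cancer-testis median -0.05 and the apoptosis inhibitor median -0.03 without a filter. The apoptosis effector median became 0.0028 with median scaling, and the epithelial-mesenchymal median -0.08 with the median of probes. The epithelial median became -0.0678 without background correction and 0.0422 without a detection filter. The endothelial median became -0.00317 without background correction, 0.0440 with median scaling, -0.00541 with the offset of 50, -0.00705 with the authors' values, -0.478 at a detection p-value of 0.05 and -0.00792 without a filter. The skeletal muscle median became -0.121, -0.162, -0.147, -0.153, -0.528 and 0.0495 under the same 6 settings. Of ratios of named genes, 710 stayed close and 110 moved, none with a reversed call. The lowest detected raw signals, 156.9 and 164.6, lay close to the medians of undetected probes, 127.3 and 129.2, which limits ratios of dim genes.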

Other observations

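The test of ATF4 targets outside the fixed list was chosen after the result was seen, since the values of CTH, PCK2 and DDIT4 were known when that list was drawn up. The test of fatty acid synthesis and other SREBP target genes was chosen after the sterol result, and its member ME1 also stood in a fixed list. Genes named here were chosen after their values were seen.

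Targets of ATF4 beyond the fixed list were lower as a group in the radiation-adapted cells. Of 30 detected ATF4 targets that the fixed list did not hold, 27 were below 0, 4 at least 2-fold lower and none at least 2-fold higher. Beside CTH, these were PCK2, a mitochondrial enzyme that makes phosphoenolpyruvate (log2 ratio -1.54), the serine synthesis gene PSPH (-1.07) and the mitochondrial folate gene MTHFD2 (-1.02). The tRNA synthetase genes GARS1 (-0.67), YARS1 (-0.58) and SARS1 (-0.56) were lower by less than 2-fold, and the amino acid transporter gene SLC1A4 was higher (0.80). A list of fatty acid synthesis and other SREBP target genes was higher: of 17 detected, 14 were above 0, with SREBF1 (1.22) and FADS1 (1.02), a fatty acid desaturase, at least 2-fold higher, and SCD at 0.95.

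One hypothesis is that the ATF4 programme was less active in the radiation-adapted cells at harvest. The list of 30 targets had a median of -0.48, below all 10000 random lists, and the 27 genes without the 3 known ones had a median of -0.47, also below all. These values are consistent with the hypothesis. A second hypothesis is that SREBP transcription factors were more active. This list had a median of 0.26, at percentile 99.5 of random lists, which is in line with it. The transcript of SREBF2, the SREBP gene that mainly drives sterol synthesis, was detected in wild type cells alone. It was at least 1.18-fold lower in the radiation-adapted cells. Its log2 signal in wild type cells, 5.89, lay close to the lowest detected one of that array, 5.55. This value therefore does not show whether the SREBF2 transcript differed. SREBP activity was not measured. Without SREBF1 and the sterol and cholesterol transport genes ACAT2, NPC1, NPC2 and TMEM97, a choice made later, 9 of 12 genes were above 0 with a median of 0.23 (percentile 97.8), and the lipid genes LPIN1 and ME1 were both at -0.23. With 1 array per line, neither list separates adaptation from the culture's state.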
